A study of Drosophila melanogaster with 12 samples.

How the data were processed

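DNA copy number was measured by comparative genomic hybridisation on Agilent custom tiling arrays with 2 channels. Per the labels, each array compared genomic DNA of 100 stage 13 egg chambers (Cy5, red) of a Drosophila melanogaster mutant with DNA of wild-type Oregon R embryos aged 0 to 2 h (Cy3, green). The females had been fed wet yeast for 2 days before dissection. The series has 5 genotypes. They are a null mutant of mus308 (2 arrays), the double mutant of lig4[169] and the mus308 null allele, here lig4_mus308 (2 arrays), a double mutant of homologous recombination, here spnA_spnB, pif1[167], here pif1 (3 arrays), and pol32[L2] over a deficiency, here pol32 (3 arrays). The deposited spnA_spnB files are named as replicates but are identical byte for byte, so they were counted as 1 hybridisation. Of 12 samples, 11 arrays were therefore used. Groups and replicate numbers came from the sample titles. Probe values at 1 of the mutated genes are not reported here. Nothing in the labels says that replicates were separate flies or separate preparations, so every p measures the spread between arrays.

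Per the file headers, the scans were quantified with Agilent Feature Extraction 10.1.1.1 (protocol CGH-v4_10_Apr08), which wrote spot and background intensity for both channels. Background was subtracted with spatial detrending, followed by multiplicative detrending and a dye normalisation with 1 factor per channel, which the values show to be linear. The green channel of the first mus308 array had no multiplicative detrending. The deposited LogRatio column is the log10 of red over green processed intensity, so that positive values mean more copies in egg chambers than in embryos. The authors also deposited a log2 value per probe for each sample. Those values follow an 11-probe running median of the scanner ratio with r between 0.678 and 0.974 and have medians between -0.055 and 0.003, so they were smoothed and centred, but the files do not state how. The headers name the older dm3 build for the array design. Probe positions in the Release 6 assembly were taken from those of the authors' files that use its sequence names, and were joined to the other arrays by probe identifier with no conversion of coordinates. All coordinates given are Release 6, counted from 1. Gene positions came from a RefSeq table of the Release 6 plus ISO1 MT assembly, with 17807 genes on the chromosome arms used. The table gives gene spans without exons or untranslated regions, and no genome sequence was used here.

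The main array design carried 173709 probes at a median spacing of 120 bp. Their density was uneven, since the window 2L 14300001 to 14350000 held 9 probes and 2L 16200001 to 16250000 held 436. The 3 pol32 arrays were each of a different design. The first shared 115735 of these probes and the second 171946, and the third was of the main design, as were all other arrays. Median spot signal ranged from 95 to 685 in green, over a background of 18 to 30, and from 133 to 2750 in red, over a background of 44 to 77. The share of probes well above background was 85.8% to 99.4% in green and 97.3% to 99.6% in red. The spread between neighbouring probes ranged from 0.36 to 0.81 on the log2 scale, with the highest values on the first pol32 array (0.81) and the first mus308 array (0.70). The number of arrays limits the precision of every value.

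The scanner ratio was multiplied up to the log2 scale. Probes were kept on an array when their green signal was well above background and neither channel was flagged as an outlier, which left 98864 to 172662 probes per array. Each array was centred on the median of its probes on the autosome arms, and X probes were centred on their own median. Kept probes were averaged in bins of 5 kb with at least 3 probes. The first pol32 array was not required to have a value, and 5850 bins on arms 2L, 2R, 3L, 3R and X were tested. Of these, 2938 had a value on the first pol32 array. With at least 1 probe per bin 16764 bins could be tested, so the bins of the main setting cover only the more densely probed part of the arms. R 4.3.3 and limma 3.58.1 fitted genotype means to all arrays together (lmFit and eBayes), with Benjamini-Hochberg adjustment over bins, a threshold of 0.05 and 2-sided tests. With only 1 spnA_spnB array, that genotype was assumed to vary between arrays like the others. The data.table package (version 1.17.8) was used to read files, and plots were drawn with Python 3.11.15 and matplotlib 3.10.9.

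The series holds no wild-type egg chambers, so genotypes were compared with one another in 5 contrasts fixed before the data were examined. These were lig4_mus308 against mus308, pif1 against pol32, spnA_spnB against the mean of the end-joining mutants (mus308 and lig4_mus308), the mean of pif1 and pol32 against the end-joining mutants, and the mean of pif1 and pol32 against spnA_spnB. The same groups recur in several contrasts, so their results are not independent of one another. Other tests and the rules for what is named were fixed at the same time. The searched regions were the 6 follicle cell amplicons known as DAFC-7F, DAFC-22B, DAFC-30B, DAFC-34B, DAFC-62D and DAFC-66D. The summit of each was the bin with the highest mean over genotypes. For each contrast the 5 runs of at least 3 adjacent bins past the threshold with the largest mean difference were named, and outside the amplicons the 5 gained and 5 depleted regions with the largest mean change. The limma SE given for a run is the mean of the SEs of its bins, not the SE of the mean difference over the run. The named genes were the 6 mutated genes and members of 5 gene lists.

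Each amplicon was described by its height, its half-width and a rotation test. The height was the mean log2 ratio of probes within 5 kb of the summit. The half-width was the distance, left arm plus right arm, over which a 10 kb running mean on a 1 kb grid stayed above 0.5 times each array's own log2 height, searched out to 300 kb. Differences of height and half-width among genotypes were tested with a permutation test of the F statistic (100000 resamples of the genotype labels, smallest possible p 1e-05), and contrasts of half-width with exact 2-sided permutation tests. DAFC-22B was too low for a half-width, so that test was adjusted over 5 amplicons and not the 6 planned. The rotation test (limma's fry) used the bins within 100 kb of the summit, adjusted over 6 amplicons and 5 contrasts. The p of fry tests whether the bins of a set move, on balance, in a single direction. It does not compare the set with other bins. A bin counted as amplified in a genotype when its log2 ratio was above 0.5 with an adjusted p under 0.05 against 0, and regions were runs of at least 3 adjacent bins with a mean beyond 0.5 in either direction.

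The scanner headers place the arrays on 7 slides, each scanned in a session of its own. The mus308 arrays, spnA_spnB and the first pif1 array shared slide 1, the second and the third pif1 array shared slide 4, and every other array was alone on its slide. With slide as a fixed term none of the 5 contrasts could be estimated. Slide was therefore fitted as a random block (correlation between arrays of a slide 0.665) in the tests of bins and in fry, but not in the permutation tests. Differences within slide 1 are given where it holds both genotypes. Array design was handled by repeating the fits on arrays of the main design.

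The procedure was tested on simulated data with independent normal noise, of the size estimated for each bin. Of bins changed by 1 on the log2 scale, between 88.1% and 100% were recovered, depending on the contrast, and of those changed by 0.5, between 32.8% and 82.1%. Between 3.29% and 8.28% of calls were false. Simulated half-widths were recovered with a median error of 2.9 kb and a largest error of 6.61 kb, and fry made 0 calls in 600 tests without a difference. The simulated amplicons were all taller than the real DAFC-30B, DAFC-34B and DAFC-62D, with less noise than the noisiest arrays. These errors may thus be too small for those amplicons. Arrays were simulated as independent of slide, so the false calls do not cover the correlation of 0.665 within a slide. Alternatives covered background correction (normexp, offset 50), loess normalisation, centring, the authors' values, the probe filter, bin size, probes per bin, a size minimum, replicate and slide blocks, array design, a trended and robust fit, the half-width definition, the amplification threshold and leaving out each array. Signals on chromosomes 4, Y and M were left out of the tests because probes there are few.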

Results

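The data are copy-number profiles of whole egg chambers, not of isolated follicle cells, the somatic cells around the oocyte that make the eggshell. Late in oogenesis these cells replicate a few loci over and over, and the resulting nested forks form gradients of copy number around each origin. Stage 13 egg chambers of 5 genotypes mutant for repair of DNA double-strand breaks were hybridised against embryo DNA on 11 arrays. There were 2 arrays each for mus308, a null mutant for DNA polymerase theta of alternative end joining, and for lig4_mus308, mutant also for DNA ligase 4 of classical end joining. The double mutant spnA_spnB, defective in homologous recombination, had 1 array and hence no replicate. The genotypes pif1, mutant for a DNA helicase, and pol32, mutant for a subunit of DNA polymerase delta, had 3 arrays each; both genes act in break-induced replication. The signal was lowest in green, at a median of 95, on the second mus308 and the first pif1 array. Correlation of bins across the genome between pairs of arrays was 0.58 to 0.96, except for pairs with the first pol32 array, at 0.45 to 0.61.

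Amplification over embryo DNA was found in all 5 genotypes at 5 of the 6 amplicons searched. Of 5850 bins, 58 were amplified in every genotype (limma, adjusted p under the threshold of 0.05), and 51 of these lay within 100 kb of a summit, with 20 at DAFC-66D, 14 at DAFC-7F, 7 at DAFC-34B, 5 at DAFC-30B and 5 at DAFC-62D. The summit bin of DAFC-66D (3L 8725001 to 8730000, Release 6) overlaps the chorion genes Cp18, Cp15 and Cp19, which encode structural eggshell proteins. The summit of DAFC-7F (X 8475001 to 8480000) lies at the chorion genes Cp7Fb, Cp7Fc and Cp36. DAFC-34B peaked at the vitelline membrane gene Vm34Ca (2L 13410001 to 13415000), DAFC-62D at yellow-g (3L 2270001 to 2275000) and DAFC-30B at CG13113 (2L 9540001 to 9545000). DAFC-22B, with 7 probes around its highest bin (2L 1830001 to 1835000), had mean log2 ratios between 0.26 and 0.53 and no bin amplified in all genotypes. The count of bins amplified in every genotype was 14 with the first lig4_mus308 array left out and 7 with the second left out.

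**Figure D1:**
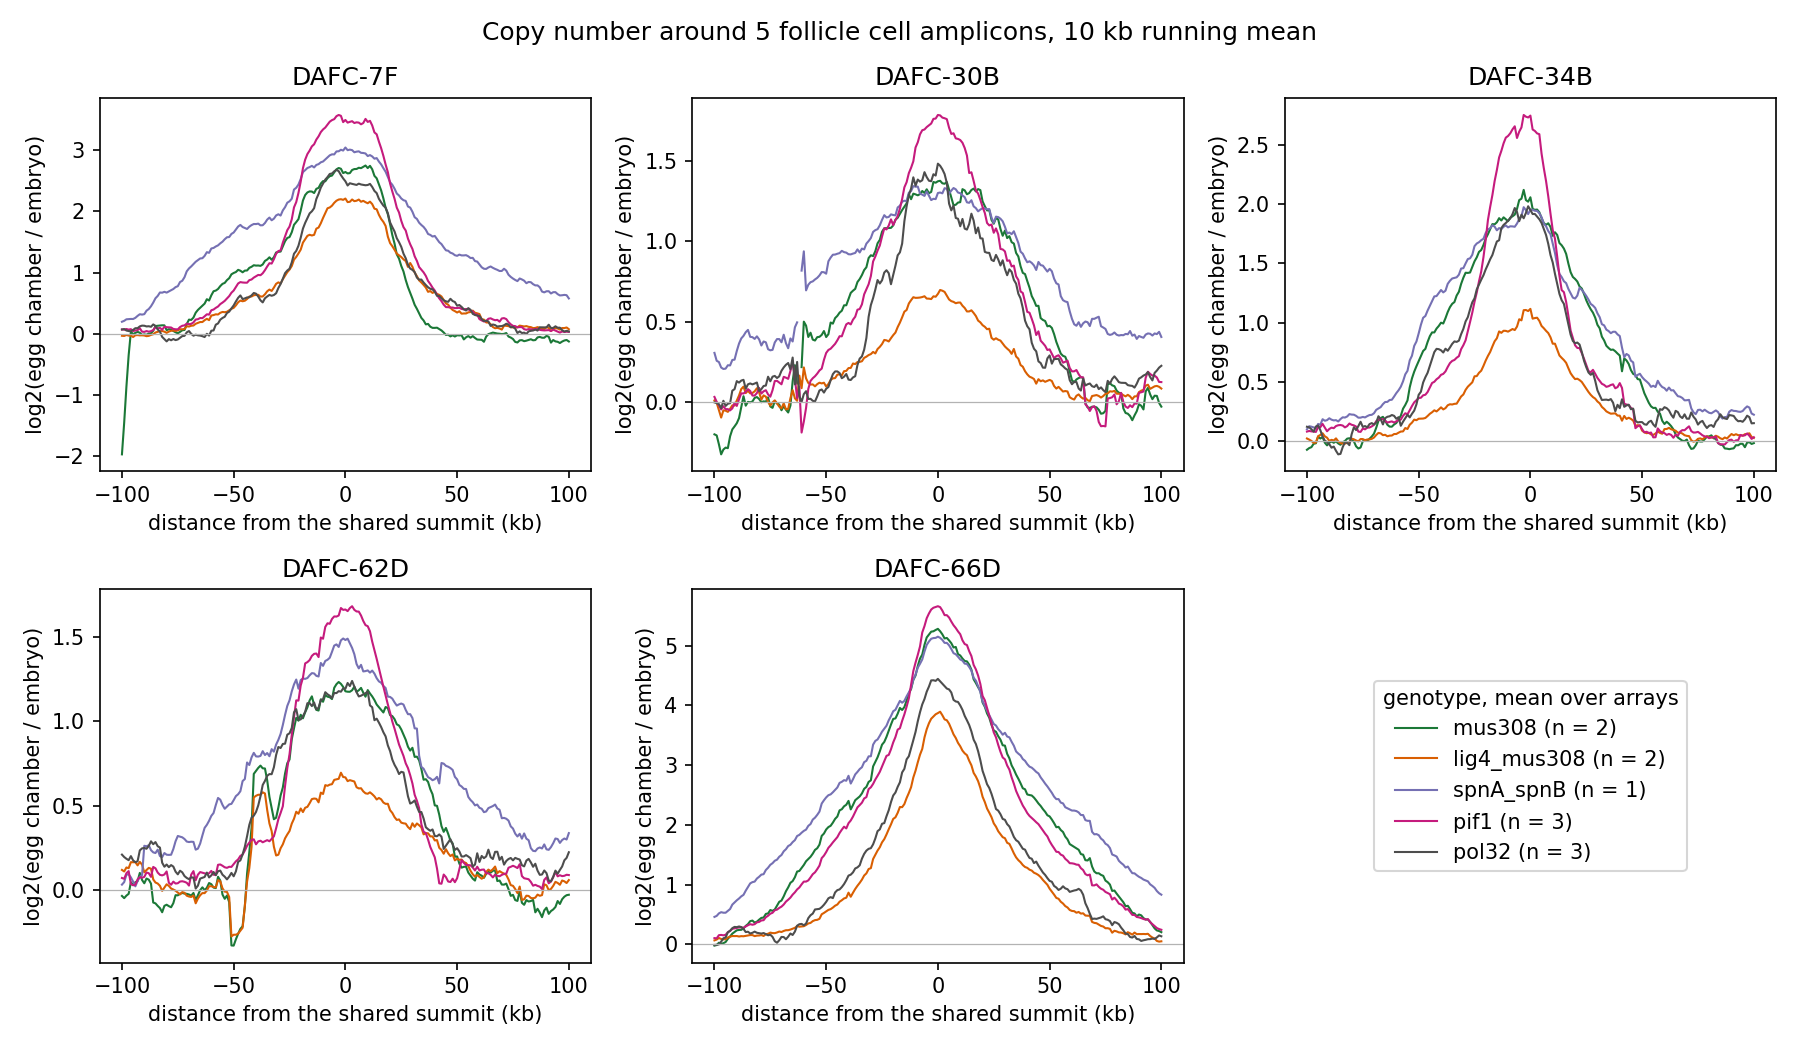
Log2 ratio of egg chamber over embryo DNA (10 kb running mean, mean over the arrays of a genotype) against the distance from the shared summit in kb, for 5 amplicons and 5 genotypes. The pif1 line peaks highest at each summit, at 5.66 for DAFC-66D. The spnA_spnB line rests on 1 array.

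Amplicon heights differed among genotypes at 3 of 6 amplicons, in permutation tests over 11 arrays. These tests left slide out, so slide and genotype are not separated in them. At DAFC-30B (adjusted p = 0.00492), DAFC-34B (0.00498) and DAFC-62D (0.0122), pif1 had the highest mean and lig4_mus308 the lowest. The log2 height of DAFC-34B was 2.75 ± 0.07 (SD, n = 3) in pif1 and 1.12 ± 0.02 (SD, n = 2) in lig4_mus308, which corresponds to 6.70-fold and 2.17-fold amplification. It was 2.06 ± 0.09 (SD, n = 2) in mus308, 1.95 in spnA_spnB and 1.95 ± 0.29 (SD, n = 3) in pol32. DAFC-30B reached 1.79 ± 0.06 in pif1 against 0.67 ± 0.04 in lig4_mus308, and DAFC-62D 1.66 ± 0.05 against 0.67 ± 0.04 (SD, n = 3 and n = 2). Means followed a similar order at the tallest amplicon, DAFC-66D, with 50.5-fold amplification in pif1, 38.9-fold in mus308, 35.5-fold in spnA_spnB, 21.8-fold in pol32 and 14.6-fold in lig4_mus308. Without the first pol32 array the log2 height of pol32 there was 5.146 in place of 4.443, level with the 5.149 of spnA_spnB. There the permutation test did not pass (adjusted p = 0.190), nor did it at DAFC-7F (0.124) or DAFC-22B (0.205). The SD of the pol32 arrays was 1.22 at DAFC-66D on the log2 scale. Without the first pol32 array, which had the largest spread between neighbouring probes, all 6 heights passed, and under normexp background correction 0 of 6 did.

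**Figure D2:**
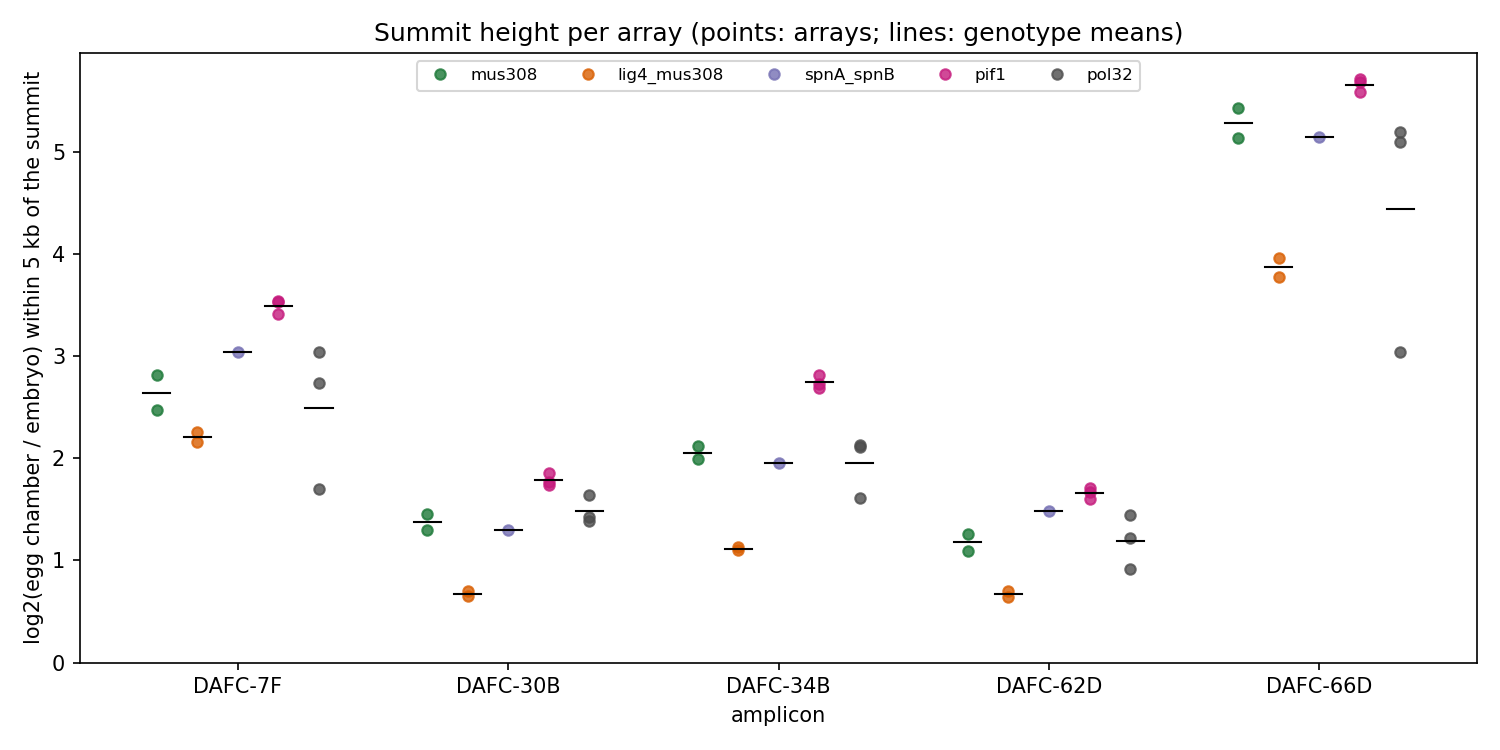
Mean log2 ratio of probes within 5 kb of the summit for each array (points) and genotype mean (lines) at 5 amplicons. At DAFC-66D the pif1 arrays lie close together (SD 0.07) and the pol32 arrays have an SD of 1.22, with the first at 3.038 and the others at 5.199 and 5.092.

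Half-widths of the copy-number gradients differed among genotypes at all 5 amplicons with a measurable width. Slide was not part of these permutation tests, so slide and genotype are not separated in them. The adjusted permutation p was 0.0468 at DAFC-7F, 0.0173 at DAFC-30B, 4e-04 at DAFC-34B, 0.000725 at DAFC-62D and 0.00215 at DAFC-66D. On the log2 scale the gradients of spnA_spnB were the widest at each of them, with 96.1 kb at DAFC-7F, 117 kb at DAFC-30B, 82.1 kb at DAFC-34B, 78.0 kb at DAFC-62D and 96.5 kb at DAFC-66D, above every other array. At DAFC-62D this was due to the left arm (44.2 kb), while the right arm, at 33.8 kb, was shorter than the 38.3 ± 0.5 kb of mus308 and the 36.4 ± 2.7 kb of lig4_mus308 (SD, n = 2 each). Measured at 0.5 times the linear excess, spnA_spnB exceeded mus308, with 104 against 68.8 kb at DAFC-30B and 49.1 against 41.5 kb at DAFC-7F, but the values were close at DAFC-34B (54.8 and 49.6 kb), DAFC-66D (32.6 and 30.2 kb) and DAFC-62D (61.29 and 60.26 kb, with the second mus308 array at 61.35 kb). Next widest on average at DAFC-30B, DAFC-34B, DAFC-62D and DAFC-66D was mus308, with 69.9 ± 0.7 kb (SD, n = 2) at DAFC-66D, compared with 48.5 ± 3.5 kb (SD, n = 2) in lig4_mus308, 59.6 ± 1.8 kb in pif1 and 49.2 ± 9.6 kb in pol32 (SD, n = 3 each). Heights and widths did not follow the same order. At DAFC-34B, pif1 combined the tallest summit with the narrowest gradient, 35.97 ± 1.19 kb (SD, n = 3), against 67.8 ± 1.5 kb in mus308 (SD, n = 2). In exact permutation tests of the 5 contrasts, 0 of 25 passed after adjustment (smallest adjusted p = 0.312, 1 under 0.05 unadjusted). In 17 of them p was already the smallest the group sizes allow, from 0.1 (3 against 3 arrays) to 0.333 (2 against 2). The tests of 6 against 4 arrays, where the smallest is 0.005, did not reach it (p from 0.024 to 0.505). Leaving out spnA_spnB, either mus308 array or either lig4_mus308 array left 3 of the 5 tests among genotypes past the threshold.

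**Figure D3:**
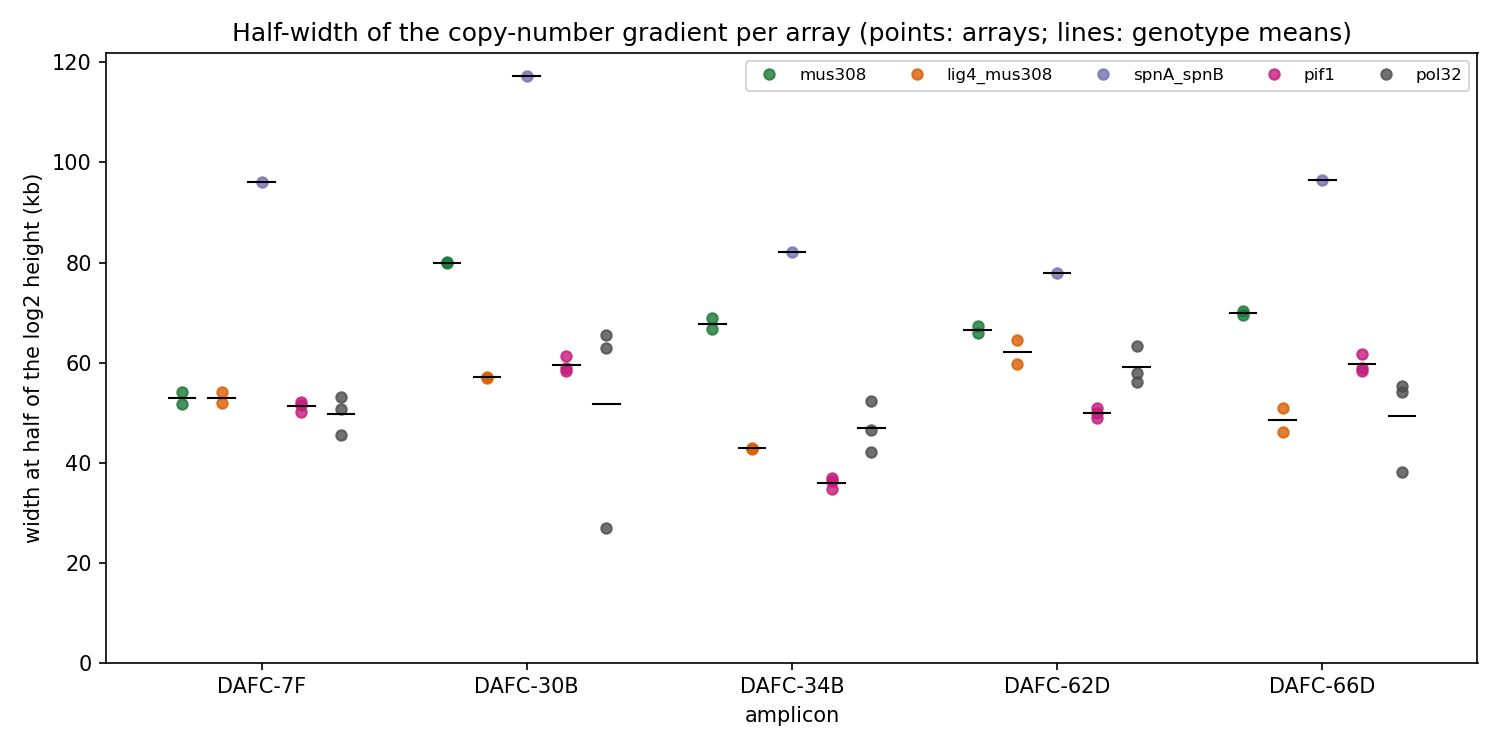
Width in kb at which the copy-number gradient stood at 0.5 times its own log2 height, for each array (points) and genotype mean (lines) at 5 amplicons. On this log2 scale the spnA_spnB array is the widest at each amplicon, with 117 kb at DAFC-30B.

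At DAFC-7F the gradient of mus308 was cut short on its right side, an observation made after the profiles were seen. The right arm of the half-width was 22.9 ± 0.1 kb and the left arm 30.1 ± 1.8 kb in mus308 (SD, n = 2), against 28.9 ± 1.8 kb and 24.1 ± 0.2 kb in lig4_mus308 (SD, n = 2), 26.1 ± 0.6 kb and 25.1 ± 0.4 kb in pif1 and 27.0 ± 1.7 kb and 22.8 ± 2.2 kb in pol32 (SD, n = 3 each). In spnA_spnB, with longer arms, the right one was also the shorter, at 41.5 kb against 54.6 kb. From 35 to 75 kb right of the summit, over Nrg and its neighbours, the mean log2 ratio was -0.08 and 0.07 on the mus308 arrays. The same distance to the left gave 0.68 and 0.82. On the right side it was 0.32 and 0.38 on the lig4_mus308 arrays, 0.37 to 0.43 on the pif1 arrays, 0.26 to 0.46 on the pol32 arrays and 1.25 in spnA_spnB. No test was run for this difference. The mus308 arrays also lacked most of the signal at X 8370001 to 8375000, centred 105 kb left of the summit, with -4.09 and -4.27 against -0.13 to 0.11 on the other arrays.

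**Figure D4:**
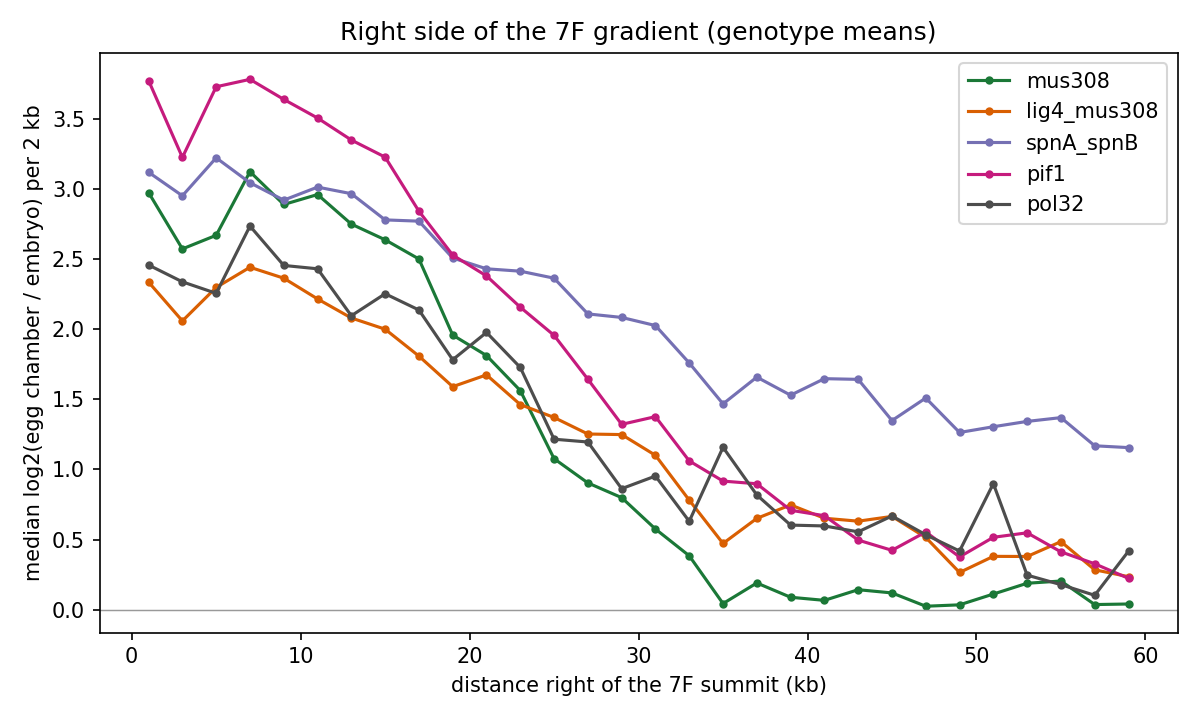
Median log2 ratio of egg chamber over embryo DNA in steps of 2 kb against the distance to the right of the DAFC-7F summit in kb (points, genotype means). The mus308 line falls from 2.50 at 16 to 18 kb to 0.04 at 34 to 36 kb and lies below the other lines from there on to about 50 kb.

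The first contrast asks what loss of DNA ligase 4 adds to loss of polymerase theta. Amplicons were lower in lig4_mus308 than in mus308. Over the bins within 100 kb of the summit the mean log2 difference was -1.02 at DAFC-66D (fry, adjusted p = 0.0044, 2 of 41 bins higher), -0.40 at DAFC-34B (0.0024, 11 of 40) and -0.31 at DAFC-30B (0.0052, 11 of 39). With slide as a random block these adjusted p were 0.0068, 0.0048 and 0.0282. DAFC-62D (-0.16, adjusted p = 0.079) and DAFC-7F (-0.08, 0.969) did not pass, and DAFC-22B passed in 0 of the 5 contrasts. Both named runs flank DAFC-66D. At 3L 8775001 to 8790000, which overlaps the formin gene Fhos and Acbp5, the log2 ratio was 0.72 in lig4_mus308 and 1.89 in mus308. The difference was -1.17 ± 0.16 (limma SE, mean over the bins of the run, n = 2 and n = 2), or 2.25-fold. At 3L 8660001 to 8680000, around the pair-rule gene hry (hairy), the log2 ratio was 0.39 against 1.48, or 2.13-fold lower. Of the eggshell genes in amplicons, 1 of 10 bins, that of CG13113, was lower over all bins tested (-0.72, adjusted p = 0.0131), and 5 were lower when adjusted over the list alone.

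In total 38 bins differed between lig4_mus308 and mus308 (limma, adjusted p under 0.05), with 27 lower and 11 higher in the double mutant. This majority turned without the second mus308 array (97 of 113 higher) and, by a few bins, without the first (7 of 13) or the second lig4_mus308 array (8 of 14) and with at least 1 probe per bin (16 of 31). Of the 202 bins near the 5 amplicons 24 differed, 23 of them lower. At an unadjusted p under 0.05 there were 405. The lig4_mus308 arrays shared no slide with mus308, so slide and genotype cannot be told apart here, and slide as a random block gave 17 bins. Leaving out single arrays other than spnA_spnB moved the count by more than 1.5 times, to between 13 (without the first lig4_mus308 array) and 113 (without the second mus308 array).

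The second contrast compares the 2 genotypes mutant for break-induced replication. DAFC-66D was higher in pif1 than in pol32, by a mean log2 difference of 0.69 over bins within 100 kb (fry, adjusted p = 0.0071, 40 of 41 bins higher, 0.0178 with slide as a random block, 0.12 under normexp background correction). The call held in 21 of 22 settings, also without the first pol32 array. The log2 height there was 3.038 on that array, 5.199 and 5.092 on the other pol32 arrays and 5.659 on average in pif1. The size of the difference at the summit thus leans on the first pol32 array. The other amplicons did not pass, with mean differences between -0.08 at DAFC-22B and 0.32 at DAFC-7F. The mean and median differed in sign at DAFC-34B (0.07 and -0.02) and at DAFC-62D (0.01 and -0.01), neither of which passed. At the Vm34Ca summit bin the difference was 0.82 ± 0.16 (limma SE, adjusted p = 0.0388), or 1.77-fold. Adjusted over the list alone, all 10 bins of eggshell genes in amplicons were higher in pif1, against 1 over all bins tested, and 2 of 5 bins of eggshell genes elsewhere were, against 0.

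The largest difference between pif1 and pol32 outside amplicons was a segment of 45 kb at 3L 7475001 to 7520000. It holds the cytochrome P450 genes Cyp316a1 and Cyp4d8 and the receptor gene mthl6, with a log2 ratio of 0.95 in pif1 and 0.05 in pol32 (difference 0.90 ± 0.10, limma SE). The hry segment on the left flank of DAFC-66D was higher in pif1 by 0.70 ± 0.12. Segments at 3R 28135001 to 28150000 (CG34354, -0.57 ± 0.08) and at 2L 16050001 to 16080000 (beat-Ia, an axon guidance gene, -0.50 ± 0.09) were lower in pif1. Altogether 97 bins differed (limma), 40 higher and 57 lower in pif1, of which 11 were near amplicons, 10 of these higher. At an unadjusted p under 0.05 there were 819. No slide held both genotypes and each pol32 array was of another design, so slide, design and genotype cannot be fully separated. Slide as a random block gave 19 bins. The count went from 27 (without the second pif1 array) to 667 (without the third pol32 array), every array but spnA_spnB moving it by more than 1.5 times. The direction of the majority depends on the setting, since the share of bins higher in pif1 was 41.2% here but between 53.6% and 72.4% in 9 of 29 alternatives, among them normexp (63.0%), slide as a random block (57.9%), arrays of the main design alone (61.6%) and leaving out the second pif1 (55.6%), the third pif1 (53.6%) or the second pol32 array (63.1%).

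The third contrast sets the recombination mutant against the end-joining mutants. Copy number within 100 kb of the summit was higher in spnA_spnB at all 5 amplicons. The mean log2 difference was 0.93 at DAFC-66D (fry, adjusted p = 0.005), 0.82 at DAFC-7F (0.0024), 0.41 at DAFC-30B (0.0029), 0.38 at DAFC-62D (0.0029) and 0.34 at DAFC-34B (0.0024). Under normexp background correction the calls at DAFC-66D (adjusted p = 0.118) and DAFC-34B (0.0754) were lost. At the 5 summit bins no difference passed, with log2 differences of 0.56 at DAFC-66D, 0.57 at DAFC-7F, 0.23 at DAFC-30B, 0.60 at DAFC-62D and 0.36 at DAFC-34B (adjusted p from 0.240 to 0.882). The largest run was the hry segment, at -67.5 to -47.5 kb from the DAFC-66D summit, with a log2 ratio of 2.06 in spnA_spnB and 0.94 in the end-joining mutants (difference 1.13 ± 0.16, limma SE, or 2.18-fold). Right of DAFC-7F, at X 8510001 to 8550000 over Nrg, the neuroglian cell adhesion gene, the values were 1.30 and 0.20, or 2.15-fold (limma SE of the log2 difference 0.16). Further runs covered Fhos to dally on the right of DAFC-66D (3L 8775001 to 8840000, 0.92 ± 0.14) and Trf2 and Miga on the left of DAFC-7F (X 8395001 to 8435000, 0.87 ± 0.14). Outside the amplicons, the 3L 7475001 to 7520000 segment was higher by 0.99 ± 0.12.

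In this contrast 134 bins differed (limma), 90 higher and 44 lower in spnA_spnB. All 47 that lay near amplicons were higher. At an unadjusted p under 0.05 there were 693. On slide 1, which spnA_spnB shared with mus308, the half-width of spnA_spnB exceeded that of mus308 by 43.1 kb at DAFC-7F, 37.4 kb at DAFC-30B, 14.3 kb at DAFC-34B, 11.4 kb at DAFC-62D and 26.6 kb at DAFC-66D. In the same order its mean difference from mus308 over bins within 100 kb was 0.784, 0.254, 0.137, 0.298 and 0.419, and that of the heights 0.401, -0.073, -0.105, 0.304 and -0.132. The adjusted fry p with slide as a random block was between 0.0022 and 0.0036, and the bin count 260. All values of spnA_spnB rest on 1 array, and the count moved to 73, 74 and 89 without the first lig4_mus308, the second lig4_mus308 and the third pif1 array, and to 339 without the first pol32 array.

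The fourth contrast compares pif1 and pol32 with the end-joining mutants. DAFC-62D was higher in pif1 and pol32, by a mean log2 difference of 0.16 over bins within 100 kb (fry, adjusted p = 0.0095, 33 of 41 bins higher). DAFC-30B (0.14, adjusted p = 0.0244) and DAFC-34B (0.13, 0.0319) were also higher. With slide as a random block the adjusted p were 0.028, 0.0661 and 0.0462, so that DAFC-30B no longer passed. Over 22 alternative settings and left-out arrays, DAFC-62D passed in 22, DAFC-30B in 14 and DAFC-34B in 10, always in the same direction. DAFC-7F (0.19, 0.129) and DAFC-66D (0.06, 0.957) did not pass. The shifts at DAFC-30B and DAFC-34B rest mostly on lig4_mus308, whose mean differences from mus308 there were -0.31 and -0.40. Against mus308 alone, pif1 over all its arrays differed by only 0.035 and -0.038, and pol32 lay below pif1 by 0.10 and 0.07. At the summit bins the differences of the fourth contrast were 0.44 at DAFC-62D (adjusted p = 0.105), 0.625 at DAFC-30B (0.00125) and 0.73 at DAFC-34B (0.0135). The run of bins at 2L 9530001 to 9550000, which holds CG13113 and CG13114, had a log2 ratio of 1.57 against 1.00 (difference 0.56 ± 0.08, limma SE, or 1.48-fold), and 3L 2250001 to 2270000, up to yellow-g, 1.29 against 0.83 (0.46 ± 0.08). Of the 10 bins of eggshell genes in amplicons, 4 were higher over all bins tested and 7 when adjusted over the list alone. Of the 5 bins of eggshell genes elsewhere 2 were higher over all bins, and 3 when adjusted over the list alone, among them Vm32E (0.47, adjusted p = 0.0153).

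Outside amplicons the 3L segment with Cyp4d8 was higher at 3L 7475001 to 7500000 (0.53 ± 0.07) and 3L 7505001 to 7525000 (0.47 ± 0.06), with mean log2 ratios of 0.49 and 0.42 over pif1 and pol32. These means come from pif1 alone, since over the whole segment pif1 stood at 0.95 and pol32 at 0.05. A segment at 2L 17105001 to 17130000 was lower (-0.91 against -0.48, difference -0.43 ± 0.08). Together 153 bins differed (limma), 95 higher and 58 lower, with 978 at an unadjusted p under 0.05. Near amplicons 15 of 16 were higher. Slide as a random block gave 114 bins, and on slide 1, where the first pif1 array can be set against mus308, the heights of pif1 were above those of mus308 by 0.89 at DAFC-7F, 0.37 at DAFC-30B, 0.63 at DAFC-34B, 0.43 at DAFC-62D and 0.40 at DAFC-66D. Over bins within 100 kb, the measure of the shift above, its mean difference from mus308 was 0.32, 0.035, -0.03, 0.075 and -0.10 in the same order. Every array but spnA_spnB and the second mus308 array moved the count by more than 1.5 times when left out, from 50 (without the first lig4_mus308 array) to 627 (without the third pol32 array), and with the authors' values 30.2% of 265 bins were higher, against 62.1% in the main setting.

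The fifth contrast compares pif1 and pol32 with the recombination mutant. Copy number within 100 kb of all 5 summits was lower in pif1 and pol32, with mean log2 differences of -0.86 at DAFC-66D (fry, adjusted p = 0.0054), -0.64 at DAFC-7F (0.005), -0.27 at DAFC-30B (0.0092), -0.22 at DAFC-62D (0.0089) and -0.21 at DAFC-34B (0.0033). With slide as a random block the adjusted p were between 0.0039 and 0.0162. Under normexp background correction 4 of these calls were lost, at DAFC-66D (adjusted p = 0.0754), DAFC-30B (0.0572), DAFC-62D (0.118) and DAFC-34B (0.131), and that at DAFC-62D also without the probe filter. All 5 named runs flank DAFC-66D or DAFC-7F. At 3L 8650001 to 8680000, with hry and Pex7, the log2 ratio was 0.65 in pif1 and pol32 and 1.84 in spnA_spnB (-1.20 ± 0.16, limma SE, or 2.29-fold). The Trf2 segment left of DAFC-7F differed by -0.99 ± 0.14, the Fhos to dally segment by -0.94 ± 0.14, and 2 segments right of DAFC-7F, over Nrg (X 8530001 to 8550000) and Trf4-1 (X 8570001 to 8585000), by -0.88 ± 0.14 and -0.58 ± 0.11. Eggshell genes in amplicons did not differ over all bins tested (0 of 10 bins, 1 higher when adjusted over the list alone), nor did those elsewhere (0 of 5 in both).

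In this contrast 75 bins differed (limma), 20 higher and 55 lower in pif1 and pol32, and 420 at an unadjusted p under 0.05. All 42 near amplicons were lower. On slide 1 the half-width of the first pif1 array was smaller than that of spnA_spnB, with differences from -27.1 kb at DAFC-62D to -56.1 kb at DAFC-30B. Its mean over bins within 100 kb was lower by 0.171 (DAFC-34B) to 0.519 (DAFC-66D), while its heights were higher by 0.124 (DAFC-62D) to 0.737 (DAFC-34B). Slide as a random block gave 103 bins. The count ranged from 30 (without the second pif1 array) to 142 (without the first pol32 array), and leaving out any lig4_mus308, pif1 or pol32 array other than the second pol32 array moved it by more than 1.5 times.

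Outside the amplicons 5 gained and 18 depleted regions were found in at least 1 genotype. Such runs could be found only where adjacent bins held enough probes, so their counts and lengths do not cover the whole arms. The gain at 2L 12865001 to 12900000, which overlaps no gene of the annotation, was found in every genotype, at log2 ratios of 0.78 ± 0.14 in mus308, 0.84 in lig4_mus308 (SD 0.001), 0.81 in spnA_spnB, 0.77 ± 0.08 in pif1 and 0.61 ± 0.04 in pol32 (SD). There, at the Cyp4d8 segment and at Vm32E, the first pol32 array had no value, so that n = 2 for pol32. A pair of gains was shared by spnA_spnB and pif1. The reference was Oregon R embryo DNA, and no other DNA of the mutant strains was hybridised. Copy number that differs between strains can therefore not be told apart from a gain made in egg chambers, for this pair or for the 2L gain. At 2R 7235001 to 7255000, with Adk3 and Gadd45, the log2 ratio was 1.24 in spnA_spnB and 1.20 ± 0.02 in pif1 (SD, n = 3), or 2.35-fold and 2.29-fold, against 0.05 ± 0.12 in mus308, 0.11 ± 0.01 in lig4_mus308 and 0.24 ± 0.17 in pol32. At the Cyp4d8 segment of 3L it was 0.98 in spnA_spnB and 0.95 ± 0.03 in pif1, and between -0.05 and 0.05 in the other genotypes. The remaining gains lie at eggshell genes. The cluster of vitelline membrane genes Vm26Aa, Vm26Ab and Vm26Ac with psd (2L 5945001 to 5970000) had log2 ratios of 0.58 ± 0.02 in pif1 and 0.50 ± 0.15 in pol32 (SD, n = 3 each), where the first array had 0.671 and the others 0.401 and 0.419. The region of Vm32E (2L 11150001 to 11190000) was gained in pif1 at 0.70 ± 0.04, with 0.35 ± 0.02 in pol32.

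Depleted regions, runs of at least 3 bins where egg chambers held less DNA than embryos, were found in every genotype except lig4_mus308. There were 17 in spnA_spnB (1085 kb in all), 9 in pif1 (710 kb), 8 in pol32 (315 kb) and 3 in mus308 (110 kb). Single bins depleted by more than 0.5 (limma, adjusted p under 0.05) were also found in lig4_mus308. They numbered 41 there, 120 in mus308, 125 in pol32 and 216 in pif1. Polyploid follicle cells are known to replicate some late-replicating regions incompletely. The deepest depletion was at 2L 16980001 to 17145000, with beat-IIIb, at log2 ratios of -0.94 in spnA_spnB, -0.89 ± 0.08 in pif1, -0.64 ± 0.16 in pol32, -0.55 ± 0.05 in mus308 and -0.30 ± 0.03 in lig4_mus308 (SD). Next came 2L 17150001 to 17310000, with beat-IIIa and Gr36a, 3L 13640001 to 13790000 within the RNA-binding protein gene bru3, 2L 17800001 to 17820000 with the cadherin gene CadN2, and X 12130001 to 12335000 with the teneurin gene Ten-a. The bru3 region stood at -0.68 in spnA_spnB and -0.25 ± 0.01 in lig4_mus308, the Ten-a region at -0.70 and -0.24 (SD 0.003). Of all 18 regions, lig4_mus308 had the mean nearest 0 in 17 and spnA_spnB the lowest mean in 16. The regions were chosen by their depth in any genotype. Of them 11 were found in 1 genotype only, mostly spnA_spnB, and none in lig4_mus308, so the choice itself favours both counts. Some are neighbouring pieces of the same stretch, so the 18 are not independent of one another. The difference in depletion between genotypes over these regions as a set was not tested.

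**Figure D5:**
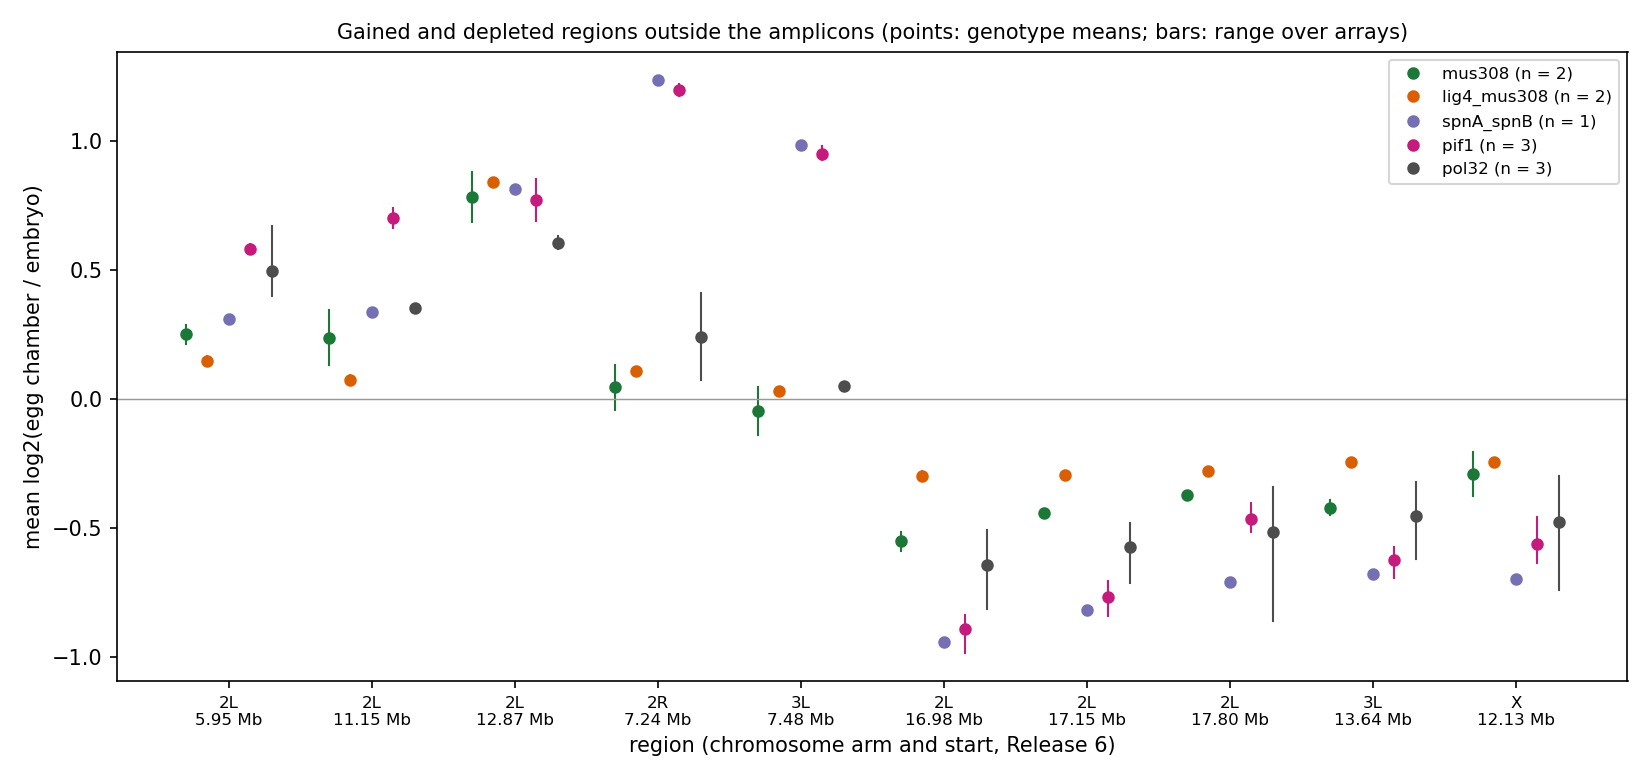
Mean log2 ratio of egg chamber over embryo DNA in the 5 gained and the 5 most depleted regions outside the amplicons (points, genotype means; bars, range over arrays). The 2R and 3L gains reach 1.24 and 0.98 in spnA_spnB and lie near 0 in mus308 and lig4_mus308, and the depleted regions are shallowest in lig4_mus308.

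The gene lists had few members under the probes. All 14 eggshell genes of the amplicons were measured, in 10 bins, and all 14 were amplified in mus308, spnA_spnB, pif1 and pol32. In lig4_mus308 13 were, and yellow-g2, a yellow-family gene of the eggshell, had a log2 ratio of 0.60 with an adjusted p of 0.0516. Cp18 and Cp15 had the highest mean over genotypes, at 4.91, and yellow-g2 the lowest, at 1.20. Of 7 measured eggshell genes elsewhere, in 5 bins, 5 were amplified in pif1 (the Vm26A genes, Vm32E and psd), 3 in pol32 (the Vm26A genes, 0 without the first pol32 array) and 0 in the others, while Femcoat and Pxd were not amplified in any genotype. The Vm26A genes share a single bin, so they count as 1 value in each genotype. None of the 4 measured repair genes (Ku80, Irbp, mre11 and tefu) was amplified, and 0 of their 4 bins differed in any contrast, whether over all bins or adjusted over the list alone. Among 3 measured replication genes, SuUR, whose product is required for underreplication in polyploid tissues, was amplified in pol32 (0.62, adjusted p = 0.00143). Its log2 ratio was 0.42 in pif1 and between 0.09 and 0.12 in mus308, lig4_mus308 and spnA_spnB. Of these 3 bins 1 was higher in pif1 and pol32 than in the end-joining mutants, over all bins and adjusted over the list alone. Adjusted over the list alone, 1 was also higher in them than in spnA_spnB. No histone gene had a tested bin.

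Probes at the mutated loci were sparse. At a probe in mus308 (PolQ in the annotation, 3R 12705523 to 12712299), at 3R 12712038 to 12712086, the egg chamber channel was not well above background on 2 of 2 mus308 arrays and on 2 of 2 lig4_mus308 arrays. Taking the background limit as the signal, copy number was at least 13.96-fold lower in mus308 and at least 14.9-fold lower in lig4_mus308 than the mean of pif1 and pol32. At the other probe in the gene, 3R 12710858 to 12710907, where the channel was not well above background on 2 and 1 of these arrays, the bounds were 8.52-fold and 9-fold. The loss was not confined to the gene. Beyond its end, at 3R 12715668 to 12715728, the bounds were 33.97-fold and 35-fold, with the channel not well above background on 2 and 1 of these arrays. Over the 2 probes in the gene the log2 ratio was 1.36 in spnA_spnB, -0.04 in pif1 and -0.12 in pol32, whose first array had no value here. The genes lig4 and spn-B had no probe within 1 kb, the nearest being 2366 and 4090 bp away. At Pif1 the only probe within 1 kb had -0.23 in pif1, and at Pol32 the mean of 3 probes within 1 kb was -0.20 in pol32, also without its first array. The only probe inside Pol32 (2L 15254980 to 15255025) had -1.048 on the second and -0.176 on the third pol32 array. The arrays of the other genotypes had 0.057 to 0.411 there. The pol32 females carried a deficiency of 2L over the mutant chromosome. In every window of 50 kb between 2L 15450001 and 15750000 the mean log2 ratio of the second and the third pol32 array was below that of the other genotypes. The differences were from -0.36 to -0.60 in 5 windows and -0.259 at 2L 15550001 to 15600000. At 2L 15650001 to 15700000 the difference came from the second array (-0.637), as the third (-0.069) and the first (0.138) lacked the loss there. The first pol32 array had a value in 3 of them, at -0.675, 0.138 and -0.03, the last in the window with most probes (158 on this array), where the other pol32 arrays stood at -0.33 and -0.64. It thus did not show the loss where it was best measured, and whether it carried the deficiency of its label is in doubt. It was kept as labelled. The Pol32 gene itself (2L 15254819 to 15256304) lies outside these windows.

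Before centring, X probes stood above autosome probes on all arrays, by 0.28 to 0.42 on the log2 scale. The genotype means were 0.32 in mus308, 0.32 in lig4_mus308, 0.38 in spnA_spnB, 0.33 in pif1 and 0.34 in pol32.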

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

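Counts of bins below follow the order of the 5 contrasts in the report, where they were 38, 97, 134, 153 and 75. Centring on all probes, no probe filter, the size minimum and the trended and robust fit kept every count within 1.5 times. Normexp background correction gave 6, 27, 19, 49 and 7 bins, 8 of 30 fry calls and 0 of 6 heights. Loess gave 77, 151, 140, 168 and 97 bins. The authors' values, with 3759 bins testable, gave 78, 199, 210, 265 and 85 bins and 5 heights. Bins of 2 kb gave 178 for pif1 against pol32 and 141 bins amplified in all genotypes (58 in the report), and bins of 10 kb 18, 73, 80, 130 and 43, with 30 amplified. At least 1 probe per bin gave 149 for pif1 against pol32 and 261 for pif1 and pol32 against the end-joining mutants. Replicate number as a block gave 28, 45, 88, 66 and 42 bins. Residuals of arrays with the same number correlated with r of -0.10 to 0.28 over 13 pairs, 2 of them above 0.1, so the numbers do not pair the arrays. Arrays of the main design alone, without the first and the second pol32 array, gave 167, 542, 608, 682 and 233 bins and 5 heights. Slide as a random block gave 17, 19, 260, 114 and 103 bins. An amplification threshold of 0.7 gave 37 bins. Except where stated, the cause was not tested.

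Further alternatives were chosen after seeing the data. Array weights, which gave the first pol32 array a weight of 0.06, led to 110, 38, 697, 194 and 223 bins. Probes well above background in both channels gave 21, 29, 73, 61 and 52. Probes on all 3 designs gave 45, 51, 98, 71 and 61. The median per bin gave 25, 42, 73, 72 and 39. Without the first pol32 and the first mus308 array, which had the largest spread between neighbouring probes, there were 99, 219, 339, 217 and 150 bins and 6 heights. Green signal was lowest on the second mus308 and the first pif1 array, with medians of 95 over a background of 20, which limits what single probes can show there, but their spread between neighbouring probes (0.444 and 0.441) was below that of the brighter first pol32 and first mus308 arrays (0.81 and 0.703).

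Leaving out each array in turn gave ranges of 13 to 113, 27 to 667, 73 to 339, 50 to 627 and 30 to 142 bins. The lowest counts came without the first lig4_mus308 array for lig4_mus308 against mus308 and for both contrasts with the end-joining mutants, and without the second pif1 array for the others. The highest came without the second mus308 array for lig4_mus308 against mus308, without the third pol32 array for pif1 against pol32 and for pif1 and pol32 against the end-joining mutants, and without the first pol32 array for both contrasts with spnA_spnB. Fry calls ranged from 7 (without spnA_spnB, which removes 2 contrasts) to 21, heights that passed from 3 to 6 (without the first pol32 array), half-widths from 3 (without spnA_spnB or any mus308 or lig4_mus308 array) to 5, and bins amplified in all genotypes from 7 (without the second lig4_mus308 array) and 14 (without the first) to 72. Where a genotype was left with 1 array, it was assumed to vary like the others.

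No fry call changed its direction past the threshold. Of 648 fry results over all settings, 597 stayed on their side of the threshold, 28 lost and 23 gained a call. The call at DAFC-34B for pif1 and pol32 against the end-joining mutants was lost in 12 of 22 settings and that at DAFC-30B in 8. Apart from these, calls were lost only under normexp, and without the probe filter at DAFC-62D for pif1 and pol32 against spnA_spnB. Half-widths passed at 5 amplicons with the linear scale or a 5 kb running mean and at 4 with a 20 kb mean or a single arm. The half-width of DAFC-22B could not be computed. The share of bins called higher moved by over 10 points with the scaling. In the report it was 28.9%, 41.2%, 67.2%, 62.1% and 26.7%. It was 33.3%, 63.0%, 89.5%, 79.6% and 42.9% under normexp, 18.2%, 47.7%, 76.4%, 67.9% and 25.8% under loess, and 9.0%, 31.2%, 51.4%, 30.2% and 8.2% with the authors' values, so that the majority turned for pif1 and pol32 against the end-joining mutants with the authors' values. For pif1 against pol32 it turned in 9 of 29 settings, which were normexp, main-design arrays (61.6%), slide as a random block (57.9%), array weights (55.3%), probes above background in both channels (72.4%), the median per bin (61.9%) and leaving out the second pif1 (55.6%), the third pif1 (53.6%) or the second pol32 array (63.1%). For lig4_mus308 against mus308 it turned in 4 of 29, which were at least 1 probe per bin (51.6%) and leaving out the second mus308 (85.8%), the first lig4_mus308 (53.8%) or the second lig4_mus308 array (57.1%).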

Other observations

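All tests below were chosen after the results were seen, except the counts of other splits of the arrays. The tests of resolution, of the baseline and of a moved segment were chosen for patterns already seen, but before their own outcome was known.

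Eggshell gene clusters outside the named amplicons had ratios above 1 in every genotype, at levels that passed the threshold for amplification in pif1 at both Vm26A and Vm32E, and at Vm26A in pol32 only with the first array (0.671, against 0.401 and 0.419). At the Vm26A cluster the mean log2 ratio was 0.21 and 0.29 on the mus308 arrays, 0.13 and 0.17 on the lig4_mus308 arrays and 0.31 in spnA_spnB. At the Vm32E region it was 0.13 and 0.34, 0.09 and 0.06, and 0.34. Low-level amplification of these clusters in all genotypes is a candidate explanation. Among stretches of 2L of the same length, 8 of these 10 values lay above the 95th percentile and the lowest was at the 88.98th (second lig4_mus308 array, Vm32E), which neither meets nor excludes it.

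Arrays carried few probes on other chromosomes. Over 10 arrays the median log2 ratio of 35 Y probes was between -4.46 and -2.34, and that of 291 probes on chromosome 4 between -0.28 and 0.10. The median of 3 mitochondrial probes was -1.45 in spnA_spnB and at most -2.38 on the other arrays.

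The lower DAFC-30B, DAFC-34B and DAFC-66D of lig4_mus308, which had passed against mus308, were weighed against compression of the ratios, dilution and slide. A common factor on all log2 ratios would keep the half-width on the log2 scale. At these 3 amplicons both lig4_mus308 arrays were narrower than both mus308 arrays by at least 18.54 kb (arrays of a genotype differed by up to 4.91 kb). This argues against compression as the whole cause, as does the 2L 12865001 to 12900000 gain at 1.072 times its mus308 log2 ratio. The 18 depleted regions (chosen by depth in the other genotypes), at a median of 0.524 times, go with compression. So does the width of DAFC-62D (gap of 1.3 kb, with 4.92 kb within genotypes). The widths of DAFC-7F overlap (gap of -2.37 kb) but do not decide, as the right side was cut short in mus308. There the left arm was 30.1 kb in mus308 and 24.1 kb in lig4_mus308, and the right arm 22.9 and 28.9 kb. Dilution by DNA of cells without amplification would keep the width at 0.5 times the linear excess. That width was smaller by at least 9.39 kb at DAFC-30B and DAFC-34B (6.43 kb within genotypes). The gaps of 3.02 kb at DAFC-66D, 0.14 kb at DAFC-62D and 1.14 kb at DAFC-7F (4.15, 6.85 and 2.95 kb within genotypes) do not decide. The shallower depletion (median factor 0.568) and the similar factors of excess copy number at the 3 amplicons (0.373, 0.369 and 0.359, with 0.466 at DAFC-62D) go with dilution. The factor of 0.686 at DAFC-7F (0.576 to 0.831 over pairs of arrays) lay above the 0.547 reached elsewhere, which would go against dilution. It cannot be relied on, since mus308 had a cut-short gradient at that amplicon and a rearrangement there stays open. The widths at DAFC-30B and DAFC-34B argue against dilution as the whole cause, and a part of it stays open. Slide was not excluded, since at DAFC-66D the pol32 arrays of different slides differed by up to 2.161 on the log2 scale, more than the difference of -1.41 between the genotypes, but this rests on the first pol32 array, without which arrays of a genotype on different slides differed by only 0.107 in pol32, 0.187 in lig4_mus308 and 0.095 in pif1. Loss of ligase 4 may lower amplification, but its effect and that of slide cannot be told apart here, as lig4_mus308 shared no slide with mus308.

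The wider gradients of spnA_spnB were weighed against a blurred array, a shifted baseline and slide. Loss of resolution would spread the edges of the 3L 7475001 to 7520000 gain, but 5 to 25 kb outside them spnA_spnB was above pif1 by only 0.031 (SD of the pif1 arrays 0.014). A raised baseline would lift bins 150 to 300 kb from the summits, where spnA_spnB differed by -0.06 from the mean of the other arrays (SD 0.098). Its half-width exceeded the widest other array of the same slide by at least 10.69 kb on the log2 scale, which argues against slide for those widths, while on the linear scale the excess was 34.78 kb at DAFC-30B and 6.11 kb at DAFC-7F but only -0.06 to 1.95 kb at the other 3, where the mus308 arrays differed by 2.18 to 6.43 kb and a wider gradient was thus not shown. Wider spread of replication forks in the recombination mutant may be considered as a hypothesis, but a fault of the only hybridisation or its DNA sample cannot be excluded without a replicate.

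The short right side of DAFC-7F in mus308 was weighed against slide and chromosome rearrangement in the strain. Relative to the mean of the other genotypes, mus308 fell between 16 and 36 kb right of the summit, and the largest 2 kb step held 0.267 of that fall, which argues against a sharp breakpoint there (this measure was redefined after a first version on the whole fall was seen). The spnA_spnB and pif1 arrays of slide 1 were higher than mus308 by at least 0.434 from 35 to 75 kb right of the summit (the mus308 arrays differed by 0.145), so slide does not account for it. A rearrangement of the strain stays open. Of 2240 windows of 50 kb, 2 were higher in mus308 than in each other genotype by at least 0.3 (3L 8000001 to 8050000 and X 17900001 to 17950000), against 0 to 11 such windows in the other genotypes. In addition, mus308 lacked X 8370001 to 8375000, 105 kb left of the summit. It was 1 of 6 bins of 5 kb that were lower in mus308 than in each other genotype by 1 or more on the log2 scale (0 to 12 such bins in the others). Since lig4_mus308 carries the same mus308 mutation and lacks the short side, an effect of mus308 alone was not shown.

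Other splits of the arrays were counted for 2 contrasts. For pif1 against pol32, 1 of 10 splits of 6 arrays, the real one, gave 97 bins, and the highest of the others gave 1, but 10 splits are too few for a share under 0.05. For the 6 pif1 and pol32 arrays against the 4 end-joining arrays, 1 of 100 drawn splits, the real one, gave 32 bins in a fit with both sides as single groups, and the highest other gave 1. The real split is the only one of 6 against 4 arrays that keeps every genotype whole, so the others mix replicates, and the count does not decide whether chance can be excluded.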
